A study of Rattus norvegicus with 28 samples.

How the data were processed

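RNA from 24 rat mesotheliomas and 4 control samples was measured on 28 arrays of a whole rat genome design in 1 colour (Cy3). Per the labels, RNA was extracted with RNeasy Mini columns and labelled with the Quick Amp kit. Per the file headers, the deposited array files were written by Agilent Feature Extraction 9.5 and hold signals as intensity on a linear scale, background-subtracted and detrended within each array, with substitute values for spots not above background. The authors also deposited a table for the whole series in log2 units, which was checked against log2 of the processed signal minus each array's 75th percentile. Over the 28 arrays the correlation was 0.999878 to 0.999997. That table holds 41090 entries, of which 78 are control probes.

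All values were computed from the array files. The log2 processed signal minus the array's 75th percentile was used as level. Control spots and spots with outlier flags were left out and spots of a probe averaged. A probe was tested if it lay well above background, by the scanner software's flag, on at least 2 of the 28 arrays, which kept 38382 of 41012 probes. For each gene name the probe with the highest mean over 28 arrays stood for the gene, giving 33254 names, of which 14882 were gene symbols that are not provisional. Probe positions refer to the rn4 build. Among genes past the threshold, other probes of the gene lay in the same direction for 191 of 199 probes in tumours against scraped, 138 of 143 in EM and 238 of 245 in SM tumours against scraped, 210 of 217 in tumours against cultured and 2 of 2 in BM against SM. None of the opposite ones passed the threshold. Signal over background sets the depth. Arrays with fewer probes above background carry less precise low levels, and the number of arrays limits the precision of each comparison.

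Groups were taken from the codes in the sample titles. The labels do not give the sex of each animal. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with a Benjamini-Hochberg adjusted p under 0.05 as threshold. Comparisons among tumours used the 24 tumour arrays with histology and fibre code as terms. The interaction used the 21 EM and SM tumours. Comparisons with controls used 5 groups (EM, BM, SM, scraped and cultured), with tumours as the mean of the histologies weighted by their number of arrays. The plan counted each control array. Because the arrays of a pair differed by less than the scanner's own error (0.826 times it for the scraped and 0.670 times it for the cultured pair), each pair was averaged to 1 sample after the data were seen. A lone control sample is assumed to vary like the tumours. Counting each control array, as planned, is given beside it.

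Gene lists were tested against all other genes with limma's camera, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over all lists and comparisons. The number of members past the test was also counted after adjustment over the list alone. The 26 lists written in advance cover mesothelial and epithelioid markers, mesenchymal and EMT genes, collagens and matrix, YAP and TEAD targets, Wnt and beta-catenin, the TGF-beta pathway, cell cycle, mesothelioma tumour suppressors, iron handling, NRF2 and antioxidant genes, inflammatory cytokines and chemokines, glycolysis and hypoxia, growth factors and receptors, MHC class II and antigen presentation, macrophages, T cells, B cells and plasma cells, neutrophils, mast cells, endothelial cells, skeletal muscle, smooth muscle, adipocytes, liver, pancreas and red blood cells. A further 9 were chosen after the data were seen: kidney, lung, brain, testis, heart, intestine, hepatocyte enzymes, pituitary, and kidney transporters and podocytes. The p-values of these 9 lists on the same arrays are therefore no independent support. The share of variance was computed with vegan 2.7.1 (adonis2 on Euclidean distances, each factor after the other, 9999 permutations). Single genes named in advance and list means were compared between tumour groups by two-sided exact permutation tests, adjusted over 8 genes or 26 lists. Tabular data were read with pandas 2.3.3 in Python 3.11.15 and with the R package data.table (1.17.8), and plots drawn with matplotlib 3.10.9.

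The comparisons, tests, 26 lists, rule for named genes and alternative settings were fixed before the data were examined. In each comparison the rule names the 10 largest rises and 10 largest falls among genes past the threshold with a symbol that is not provisional and well above background on at least 50% of the arrays of the higher group (5 each way for BM, fibre codes and the interaction). It adds up to 4 members of each list past the test. Ccn2 (Ctgf), Ctnnb1, Msln, Wt1, Cdkn2a, Cdkn2b, Nf2 and Bap1 are named whatever their result. Members that passed only over their list alone, genes given by their level and members of the 9 later lists fall outside the rule and were chosen after their values were seen. A fold is given as a lower bound where no array of the lower group lay well above background.

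The alternatives fixed in advance were normexp background correction (offset 50) with quantile normalization, quantile normalization of processed signals, median scaling, the deposited log2 values, no filter or a filter on 50% of the arrays, each probe or the mean of probes, eBayes with trend and robust, an additional 2-fold threshold, slide or scan date as a block, the replicate number as a block, the Uty level as covariate, leaving out each array (only each control array for comparisons with controls), models without the other factor or without BM tumours, each fibre code alone, and smaller groups in the model. Chosen after the data were seen were array weights, scan day in place of slide as the block of the fibre comparisons, and leaving out 2, 3 or 6 tumour arrays that stood apart. Averaging the control pairs was also chosen then, and the comparisons as first planned are the alternative with each control array counted. The model was tested on simulated data with 200 changed genes of 20000. Between SM and EM tumours it recovered 18%, 88%, 98% and 100% of differences of 1, 2, 4 and 8 log2 units, with 10 false calls. For tumours against scraped it recovered 0%, 12%, 60% and 100%, with 5 false calls. The simulated spreads were drawn from a set range with independent noise, without slide effects or outlying arrays. They were not taken from these arrays, where the median SE was 0.516 and 1.16 in the 2 comparisons. The shares therefore do not give the power in these data. Nothing was left out of the main comparisons besides the spots and probes named above.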

Results

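Total RNA of 24 rat peritoneal mesotheliomas and of 4 control samples was measured on 28 single-colour (Cy3) whole rat genome arrays. Per the labels, the tumours grew after intraperitoneal injection of asbestos in F1 hybrids of Brown Norway rats and a second inbred strain. Each tumour title carries a fibre code (Amo, Chr or Cro) and a histology code (EM, BM or SM). In this field the codes commonly stand for amosite, chrysotile and crocidolite and for epithelioid, biphasic and sarcomatoid mesothelioma, but the labels spell out neither set. The groups were 2 Amo_EM, 1 Amo_BM, 5 Amo_SM, 3 Chr_EM, 2 Chr_BM, 3 Chr_SM, 4 Cro_EM and 4 Cro_SM tumours, so 9 EM, 3 BM and 12 SM. The controls were 2 arrays labelled knife-scraped mesothelium (Brown Norway) and 2 labelled cultured mesothelium (the second parental strain). Levels are log2 signals relative to each array's 75th percentile. That percentile lay between 39.4 (Chr_BM 6) and 3431 (Cro_SM 3) signal units, and 34.0% (Chr_BM 6) to 91.0% (Amo_BM 3) of probes lay well above background. The control arrays held 51.4% to 54.0% such probes.

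The arrays sat on 7 slides of 4. Slides 1 and 2 held the Amo tumours, 3 and 4 the Chr tumours, 5 and 6 the Cro tumours and slide 7 the controls. The control slide was scanned on a day of its own, so controls cannot be told apart from slide, scan day and strain. Fibre codes had slides of their own, so fibre cannot be told apart from slide either. The median difference over all genes, in log2 units, was -0.21 for SM minus EM, 0.47 for BM minus EM, 0.68 for BM minus SM and 0.25 for tumours minus scraped. Scaling on the array median moved these to -0.07, 0.10, 0.18 and -0.21. Each list of genes was therefore tested against all other genes.

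The comparison of SM with EM tumours asks what separates the 2 pure histologies. Ccn2 (also Ctgf, connective tissue growth factor), a secreted matricellular protein, was higher in SM tumours. Its level was 5.38 ± 1.04 (SD, n = 12) in SM and 3.13 ± 1.65 (n = 9) in EM tumours, a difference of 2.25 log2 units. The two-sided exact permutation p was 0.00111, and 0.00885 after adjustment over the 8 genes named in advance. All 12 SM tumours lay above the EM median and 5 above the highest EM tumour. Ccn2 was read by 1 probe on chromosome 1 (21327574 to 21327633, rn4). In the limma model with fibre code as a term the difference was 2.33 ± 0.63 (SE; 95% confidence interval 1.1 to 3.57), with an adjusted p of 0.379 over 33254 genes. Within the 5 slides that held both histologies it was 0.40 to 4.72, higher in SM in each, and 1.99 with slide as a block. Without 6 arrays singled out after seeing the data (Amo_EM 5, Chr_BM 2, Chr_EM 3, Chr_BM 6, Cro_EM 6 and Chr_EM 7) the difference was 1.39, exact permutation p = 0.0383, adjusted p = 0.306.

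**Figure D1:**
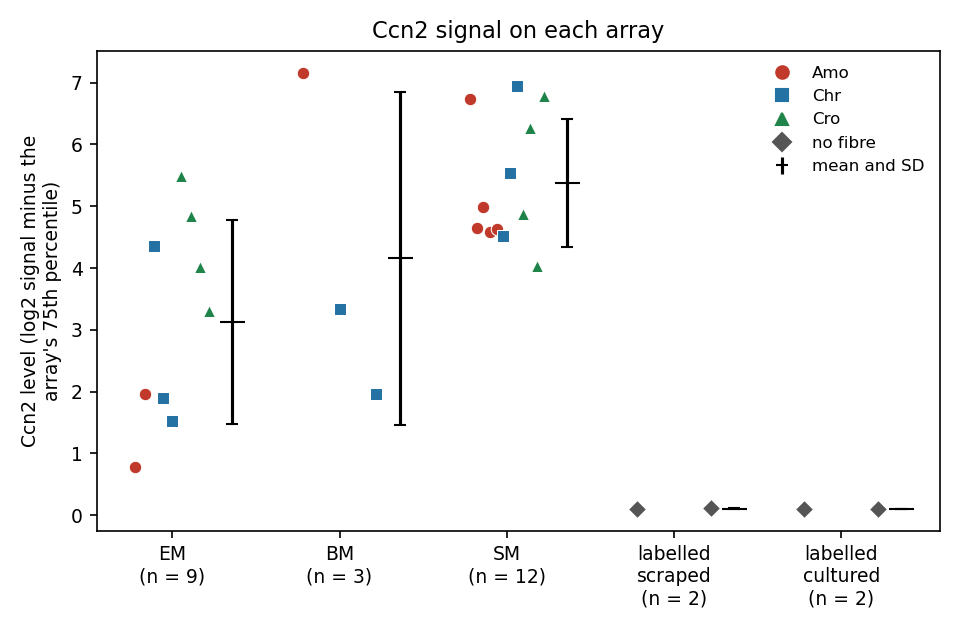
Ccn2 level on each of the 28 arrays (y axis: log2 signal minus the array's 75th percentile), by histology code and for the arrays labelled scraped and cultured mesothelium; points are arrays, marked by fibre code, and bars give the mean and SD of each group. Means were 3.13 in 9 EM, 4.16 in 3 BM and 5.38 in 12 SM tumours, against 0.11 and 0.10 on the control arrays.

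Matrix genes leaned toward SM tumours as a group. Of 22 measured genes for collagens and matrix, 21 had a positive SM minus EM difference, with a median of 1.39 log2 units (camera adjusted p = 6.6e-14; adjusted p = 0.327 with an estimated correlation). 9 of the 22 rose when adjusted over the list alone, and none over all genes. They included Lum (lumican, 2.91 ± 0.96, SE), Thbs2 (a matricellular thrombospondin, 2.87 ± 0.95), Tnc (tenascin C, 2.31 ± 0.74) and Lox (the collagen cross-linking enzyme lysyl oxidase, 2.25 ± 0.90). Mesenchymal genes were positive for 19 of 21 members, median 1.07 (adjusted p = 5.2e-07; adjusted p = 0.434 with an estimated correlation), and none passed alone. The TGF-beta list had a median of 0.48 (adjusted p = 0.000259; adjusted p = 0.327 with an estimated correlation). Within slides the matrix median was -0.17 to 3.23, positive in 4 of 5 slides, and 1.09 with slide as a block. The mesenchymal median was -0.33 to 2.7, positive in 3 of 5. On each tumour's list mean, exact permutation tests gave p = 0.00458 for the matrix list, adjusted p = 0.0835 over 26 lists. That was the lowest adjusted p, so none of the 26 lists passed between SM and EM tumours on list means.

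Macrophage genes also leaned toward SM tumours. All 13 were positive, with a median of 1.01 (camera adjusted p = 4.9e-11; adjusted p = 0.307 with an estimated correlation). Csf1r (the receptor for macrophage colony-stimulating factor, 1.39 ± 0.41) and Lyz2 (lysozyme, 2.15 ± 0.59) rose when adjusted over the list alone (adjusted p = 0.0170 for both). All 12 genes of MHC class II and antigen presentation were positive, median 0.78 (adjusted p = 1.6e-06; adjusted p = 0.423 with an estimated correlation). Il18 (an inflammasome cytokine) differed by 1.23 ± 0.34 and Fzd1 (a Wnt receptor) by 1.83 ± 0.49, each past its own list alone. The cell cycle list was positive for 29 of 30 genes, median 0.71 (adjusted p = 1.6e-10; adjusted p = 0.565 with an estimated correlation). Without the 6 arrays named above the lists of cell cycle (adjusted p = 0.831, direction down), TGF-beta (0.586), Wnt (0.772), inflammatory genes (0.558), glycolysis (0.603, direction down) and growth factors (0.584) were no longer called. Those of matrix (1.0e-08), macrophages (4.2e-09), MHC class II (0.0171) and mesenchymal genes (0.00383) were. With normexp and quantile normalization Wnt (adjusted p = 0.106), NRF2 (0.0538), growth factors (0.0979) and endothelial cells (0.131) were not called. Within slides the macrophage median was -0.24 to 2.40 and the cell cycle median -0.08 to 1.71, each positive in 4 of 5. Other called lists held less there: MHC class II (-0.69 to 2.37), inflammatory (-0.19 to 2.09) and NRF2 genes (-0.67 to 0.73) were positive in 3 of 5 slides, and Wnt (-0.46 to 0.76) and growth factors (-0.16 to 1.13) in 2 of 5.

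Skeletal muscle genes went the other way. All 14 were lower in SM tumours, median -3.05 (camera adjusted p = 8.1e-10; adjusted p = 0.367 with an estimated correlation), and 9 fell when adjusted over the list alone. Pvalb (parvalbumin) differed by -4.52 ± 1.18, Myh2 (a fast myosin heavy chain) by -4.44 ± 1.28 and Ckm (muscle creatine kinase) by -3.82. The list was lower in SM tumours on each of 5 slides, by -6.01 to -0.85. Its mean level was 5.07 in Amo_EM 8, 3.0 in Cro_EM 2 and 2.30 in Chr_EM 7. The other EM tumours lay at -3.46 (Cro_EM 1) to -0.51 (Cro_EM 8). These lay within the range of SM tumours, which was -4.30 (Cro_SM 7) to 1.14 (Amo_SM 6).

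**Figure D2:**
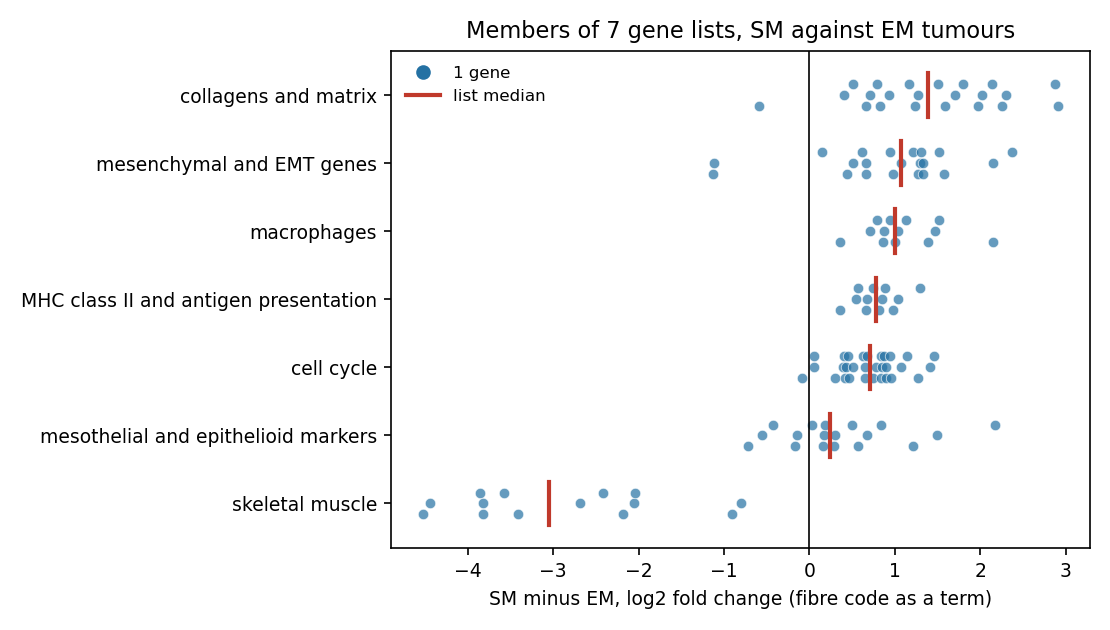
SM minus EM log2 fold change of each measured member of 7 gene lists, from the limma model with fibre code as a term; each point is 1 gene and the red line the median of its list. Medians were 1.39 for collagens and matrix, 1.07 for mesenchymal genes, 1.01 for macrophages, 0.78 for MHC class II, 0.71 for cell cycle, 0.24 for mesothelial markers and -3.05 for skeletal muscle.

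Of the other genes named in advance, Msln (mesothelin) differed by 1.5 ± 1.19 between SM and EM tumours and Wt1 (a mesothelial transcription factor) by 0.57 ± 0.74. Cdkn2a (the p16 and Arf locus, often lost in mesothelioma) differed by -1.02 ± 0.54 and Cdkn2b by -0.51 ± 0.53. Ctnnb1 (beta-catenin), Nf2 and Bap1 (both tumour suppressors of mesothelioma) differed by 0.52 ± 0.46, 0.14 ± 0.48 and 0.13 ± 0.37. None of these 7 passed, with exact permutation adjusted p of 0.598 or more. The sign for Msln and Wt1 rested on Amo_EM 5, without which the differences were -0.20 and -0.27. Lists called with small medians were Wnt (0.45; adjusted p = 0.573 with an estimated correlation), NRF2 (0.26; 0.565), inflammatory (0.63; 0.565), glycolysis (0.35; 0.602), growth factors (0.37; 0.434) and endothelial cells (0.27; 0.637), where the second number is again the adjusted p with an estimated correlation. Uncalled lists had medians of 0.24 for mesothelial markers, 0.02 for YAP targets, 0.17 for tumour suppressors, 0.24 for T cells, -0.25 for B cells, -0.30 for neutrophils and -0.79 for mast cells. They were 0.43 for smooth muscle, -0.21 for adipocytes, -1.51 for liver, -0.12 for pancreas and 0.04 for red blood cells, and iron handling had a median of 0.16 against a mean of -0.07. With slide as a block YAP targets (median 0.18, adjusted p = 0.0187) and smooth muscle (0.46, adjusted p = 0.0368) were called higher and liver (-2.5, adjusted p = 0.00264) lower in SM tumours, so for these the result depends on the model. Within slides the YAP median was -0.39 to 0.68 and the smooth muscle median -0.37 to 1.47, each positive in 4 of 5, and the liver median -9.11 to 0.03, positive in 1 of 5. Of lists chosen after the data were seen, pituitary (-1.22; 0.401) and brain (-0.77; 0.265) were called, and heart (-0.37), testis (-0.45), kidney (-0.19), kidney transporters and podocytes (-0.16), lung (-0.55), intestine (0.26) and hepatocyte enzymes (-0.86) were not. Over all genes limma called 0 between SM and EM, with 2262 at an unadjusted p under 0.05. Leaving out Amo_BM 3 gave 1 and leaving out Chr_BM 2 gave 2, and no other single array gave any.

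The 3 BM tumours were compared with the other histologies in the same limma model. Cell cycle genes were lower in BM tumours than in SM tumours for 30 of 30 members, with a median of -2.0 (camera adjusted p = 7.9e-20; adjusted p = 0.327 with an estimated correlation). 18 of them fell when adjusted over the list alone, among them Aurkb (a mitotic kinase, -3.20 ± 0.99), Ttk (a spindle checkpoint kinase, -3.10 ± 0.83), Mcm6 (a replication helicase subunit, -3.08 ± 0.91) and Ccnb1 (cyclin B1, -3.0 ± 0.84). Macrophage genes were lower by a median of -1.86 (adjusted p = 3.9e-09; adjusted p = 0.337 with an estimated correlation), with Msr1 (-2.84), Itgam (-2.76), Cd163 (-2.74), Csf1r (-1.97) and C1qc (-1.86) past the list alone. The matrix list had a median of -2.08 (adjusted p = 2.2e-09; adjusted p = 0.449 with an estimated correlation) and glycolysis -1.33 (adjusted p = 8.2e-08; adjusted p = 0.434 with an estimated correlation). On the 3 slides with both histologies the cell cycle median was -4.94 to 0.05, the macrophage median -5.12 to 0.12 and the matrix median -5.27 to -0.63. Without the 6 arrays named above, which leaves Amo_BM 3 as the 1 BM tumour, macrophages (adjusted p = 0.115), mesenchymal genes (0.192), MHC class II (0.721), Wnt (0.178), inflammatory genes (0.245) and smooth muscle (0.215) were not called. Msln was 3.80 ± 3.17 (SD, n = 3) in BM and 6.96 ± 0.60 (n = 12) in SM tumours, exact permutation p = 0.00879, adjusted p = 0.0352 over 8 genes. Bap1 was -0.76 ± 0.40 against 0.14 ± 0.40, exact permutation p = 0.00659, adjusted p = 0.0352. In limma with fibre code as a term neither passed, at -2.79 ± 1.79 (SE, adjusted p = 0.297) for Msln and -0.84 ± 0.56 (adjusted p = 0.313) for Bap1. Msln lay at 0.35 on Chr_BM 2 and 4.46 on Chr_BM 6 but at 6.59 on Amo_BM 3, inside the range of SM tumours, and its limma difference was -1.04 without Chr_BM 2 and -4.91 without Amo_BM 3. The 3 lowest Bap1 levels of all tumours were on the 3 tumour arrays of lowest signal, Cro_EM 6 (-2.04), Chr_EM 3 (-1.83) and Chr_BM 6 (-1.12), of which 1 is BM. Erbb3 (a receptor tyrosine kinase, 2.76 ± 0.65) and Wwc1 (a Hippo pathway scaffold, 3.22 ± 0.86) rose within their lists alone.

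Kidney genes were high in 1 of the 3 BM tumours. The kidney mean was 5.54 in Chr_BM 2, -2.25 in Amo_BM 3 and -0.97 in Chr_BM 6. All 5 members of a kidney list chosen after the data were seen were higher in BM than in SM tumours when adjusted over the list alone, with a median of 5.55 (camera adjusted p = 1.8e-05; adjusted p = 0.152 with an estimated correlation). Slc34a1 (a proximal tubule phosphate transporter) differed by 6.20 and Umod (uromodulin) by 5.62. A second kidney list of transporters and podocyte genes passed for 8 of 10 members alone, median 3.79 (adjusted p = 0.256 with an estimated correlation). Both kidney lists were chosen after the data were seen, so their p-values are no independent support. Over all genes 84 were higher in BM than in SM tumours and 0 lower, 7728 at an unadjusted p under 0.05. The largest rises among named symbols were AKR1C3l1 (6.42 ± 1.39), Slc7a13 (6.15 ± 1.26), Gba3 (5.90 ± 1.08), Slc22a24 (5.59 ± 1.02) and En2 (5.39 ± 1.09). No SM array was well above background for the last 4, and 2 of 3 BM arrays were for the first 3 of them and 3 for En2. Group means without the fibre term, with SM arrays at their floor, give at least 96.4, 65.3, 60.6 and 47.1-fold, which exceeds the limma estimates because these hold the fibre code constant. With quantile normalization the differences fell to 3.63, 3.39, 4.15 and 4.21, so the bounds hold for the main scale alone. They also rest on the full set of arrays: with 1 tumour left out, none of these genes passed in 11 of 24 cases. None of these 5 passed with normexp and quantile normalization, with quantile normalization of processed signals or with median scaling. Of the 84, 59 were not well above background on any SM array, and over all genes the median difference was 2.14 among the dimmest 10% in SM tumours against -0.49 among the brightest 10%.

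That count rested on single arrays: in 11 of 24 cases leaving out 1 tumour gave 0. These were Amo_SM 2, Amo_SM 6, Amo_SM 7, Chr_EM 1, Chr_SM 4, Chr_SM 5, Chr_SM 8, Cro_EM 1, Cro_SM 3, Cro_SM 5 and Cro_SM 7. It was 5502 without Chr_BM 2, 541 without Chr_EM 3, 238 without Amo_SM 1, 192 without Cro_EM 6, 150 without Amo_BM 3, 137 without Cro_EM 8, 43 without Chr_EM 7 and 11 without Chr_BM 6. Between BM and EM tumours limma called 0 genes (2372 at an unadjusted p under 0.05), and 30 without Cro_EM 6. Cell cycle genes were lower in BM than in EM tumours, median -1.23 (camera adjusted p = 7.2e-15, adjusted p = 0.434 with an estimated correlation). The kidney list, chosen after the data were seen, was higher, median 5.03 (camera adjusted p = 3.3e-08, adjusted p = 0.0606 with an estimated correlation). Lower in BM than in EM tumours with the preset correlation alone were glycolysis (-0.99), skeletal muscle (-1.56), iron handling (-0.49), mesothelial markers (-0.66), macrophages (-0.58), matrix (-0.78), tumour suppressors (-0.09), liver (-1.08), mast cells (-1.28) and inflammatory genes (-0.03), and TGF-beta (-0.06), whose sign turned with normexp. Without the 6 arrays named above, matrix (adjusted p = 0.186), liver (0.707), inflammatory genes (0.40), iron handling (0.0697), TGF-beta (0.0738) and macrophages (0.680, direction up) were not called between BM and EM tumours. With slide as a block tumour suppressors were not called (adjusted p = 0.0754, median 0.17). Against SM tumours this held for TGF-beta (-0.95), iron handling (-0.76), mesenchymal genes (-1.08), mesothelial markers (-0.90), inflammatory genes (-0.43), tumour suppressors (-0.47), MHC class II (-0.45), Wnt (-0.15) and smooth muscle (-0.48), the last not called with slide as a block (adjusted p = 0.0578). Of the 12 lists written in advance and called between BM and EM tumours 7 stayed called with normexp, and of the 13 between BM and SM tumours 9. On list means exact permutation tests passed for none of 26 lists, with lowest adjusted p of 0.982 for BM against EM and 0.0686 for BM against SM. Ccn2 differed by 1.57 ± 0.98 for BM minus EM and -0.77 ± 0.95 for BM minus SM, adjusted p = 0.598 and 0.588 by limma.

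The comparison of fibre codes asks whether the tumours carry a trace of the fibre that induced them. Each code had slides of its own, so a difference between codes cannot be told apart from one between slides. Within a scan day each code lay on a single slide, so comparisons within a day do not remove slide. Liver genes were highest in Chr tumours. The 12 liver genes differed by a median of 3.98 between Chr and Cro (camera adjusted p = 3.8e-18; adjusted p = 0.123 with an estimated correlation) and by -3.69 between Amo and Chr (adjusted p = 9.6e-13; adjusted p = 0.221 with an estimated correlation). Of these, 9 rose in Chr against Cro and 8 fell in Amo against Chr when adjusted over the list alone. Apoa1 (the main protein of high-density lipoprotein) differed by 6.43 ± 1.40 and -5.06 ± 1.36, Fga (fibrinogen) by 4.62 and -4.52 and Serpina1 by 4.45 and -4.10. The list mean was 6.64 in Chr_EM 7, 2.64 in Chr_SM 5 and 0.61 in Chr_EM 3, and below 0 in the other 21 tumours. Within scan day 4 the median was 6.80 for Chr minus Cro. Within scan days 2 and 4 it was -1.35 and -6.84 for Amo minus Chr.

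Lists of MHC class II and macrophage genes were lower in Chr and in Amo tumours than in Cro tumours, and T cell genes in Chr tumours. The lists of MHC class II (median -1.15; adjusted p = 1.6e-06), macrophages (-0.93; 3.7e-07) and T cells (-0.72; 1.7e-05) were lower in Chr than in Cro tumours for every measured member. These calls were lost in camera with an estimated correlation (adjusted p = 0.423, 0.434 and 0.337 with an estimated correlation). Gzmb (granzyme B of cytotoxic lymphocytes) fell by 2.94 ± 0.86 log2 units over the list alone (adjusted p = 0.0296). Amo tumours differed from Cro tumours by -0.85 in MHC class II (adjusted p = 7.2e-05; adjusted p = 0.525 with an estimated correlation) and -0.95 in macrophages (adjusted p = 4.0e-05; adjusted p = 0.565 with an estimated correlation). Red blood cell genes were lower in Amo tumours than in Cro (-1.52; adjusted p = 0.434 with an estimated correlation) and Chr tumours (-1.2; adjusted p = 0.449 with an estimated correlation). Within scan day 4 the MHC class II and macrophage medians were -1.12 and -1.09 for Chr minus Cro and -1.72 and -1.61 for Amo minus Cro. MHC class II was not called for Chr minus Cro without the 6 arrays named above (adjusted p = 0.187). For Amo minus Cro T cells (median -0.23), B cells (-0.44), neutrophils (-0.60) and mast cells (0.44) were not called, and mast cells were higher without the 6 arrays (adjusted p = 0.0115). With scan day as a block T cells were lower for Amo minus Cro (median -0.60, adjusted p = 0.0221). For Chr minus Cro B cells (-0.42), neutrophils (-0.43) and mast cells (-0.13) were not called.

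**Figure D3:**
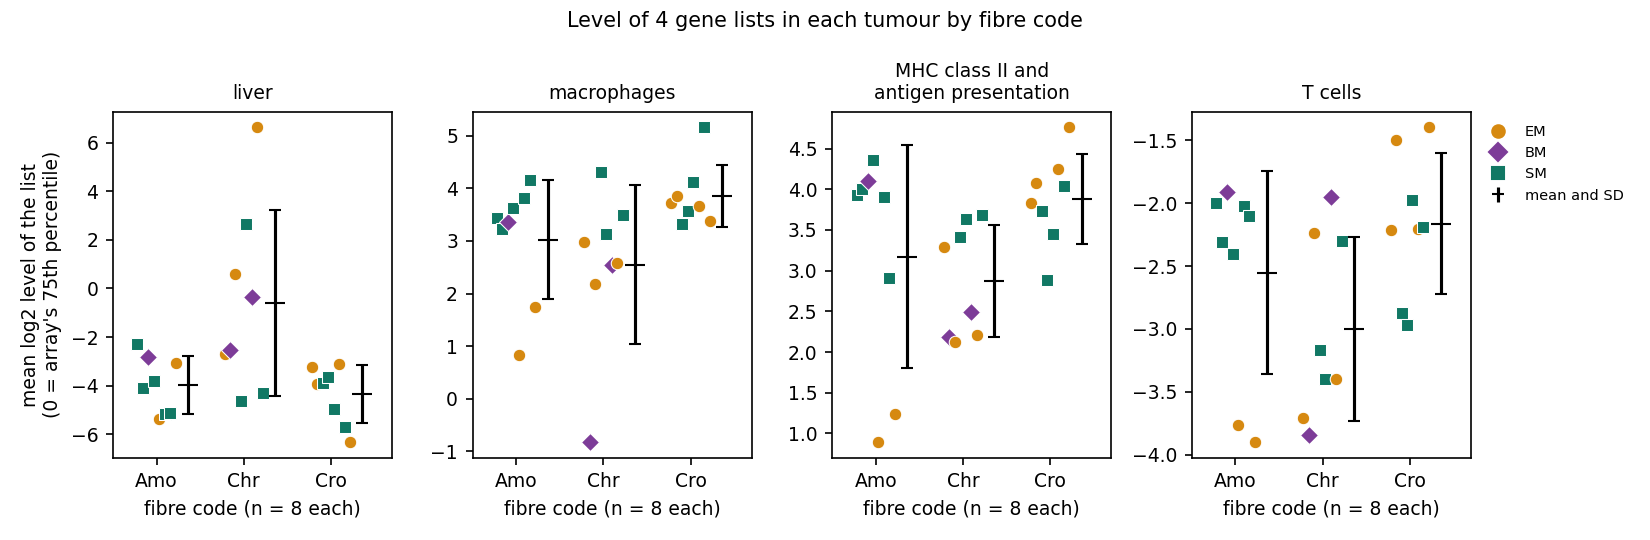
Mean log2 level of 4 gene lists in each of 24 tumours (y axis: 0 is the array's 75th percentile) by fibre code; points are tumours, marked by histology code, and bars give the mean and SD of 8 tumours. The liver mean was 6.64 in Chr_EM 7, and the macrophage mean 5.16 in Cro_SM 7 and -0.82 in Chr_BM 2.

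No gene passed between fibre codes. Limma called 0 genes each for Amo against Chr, Amo against Cro and Chr against Cro, with 941, 1114 and 1095 at an unadjusted p under 0.05, and leaving out any single tumour gave 0. Exact permutation tests on list means reached no adjusted p under 0.05, the lowest being 0.543, 0.510 and 0.121. Ccn2 was 4.43 ± 2.16 (SD, n = 8) in Amo, 3.76 ± 1.93 in Chr and 4.95 ± 1.18 in Cro tumours, with Chr minus Cro at -1.29 ± 0.74 (SE; 95% confidence interval -2.74 to 0.16). Between Amo and Chr the cell cycle list (0.46; adjusted p = 0.637 with an estimated correlation), skeletal muscle (1.32; 0.602), glycolysis (-0.49; 0.602), matrix (-0.56; 0.720), YAP targets (-0.35; 0.449) and T cells (0.43; 0.602) were called only with the preset correlation. Between Amo and Cro this held for mesenchymal genes (-0.95; 0.602), glycolysis (-0.57; 0.565), TGF-beta (-0.79; 0.449), skeletal muscle (0.95; 0.645) and matrix (-0.88; 0.71). Between Chr and Cro it held for mesothelial markers (0.55; 0.589) and cell cycle (-0.45; 0.810). With scan day as a block the calls of matrix for Amo minus Cro (median -0.17, adjusted p = 0.864) and of cell cycle for Chr minus Cro (-0.20, adjusted p = 0.448) were lost. Newly called with that block were, for Amo minus Cro, mesothelial markers (0.69, adjusted p = 0.0283), cell cycle (0.26; 0.0129), tumour suppressors (0.47; 0.0335), liver (1.47; 0.000615) and pancreas (-1.06; 0.0477). On scan day 4, the only one with both codes, the medians were 0.43, 0.02, 0.59, -0.05 and -1.10, so liver and cell cycle did not differ there in the same way. For Chr minus Cro these were matrix (0.31, adjusted p = 0.0184) and pancreas (-1.01; 0.00170), with 0.96 and -0.94 on scan day 4. Without the 6 arrays named above, cell cycle (adjusted p = 0.394, direction down) and matrix (0.391) were not called for Amo minus Chr, nor mesenchymal genes (0.0610) and matrix (0.156) for Amo minus Cro, and cell cycle turned higher for Chr minus Cro (0.00227). Whether the SM minus EM difference depends on the fibre was tested as an interaction over the 21 EM and SM tumours. Limma called 0 of 33248 genes, with 2080 at an unadjusted p under 0.05. The count was 118 without Amo_EM 8, 2 without Chr_EM 7 or Cro_EM 6 and 1 without Amo_SM 4 or Cro_SM 3. Ccn2 had an interaction p of 0.0855 by limma, adjusted p = 0.375 over 8 genes. Histology accounted for 14.8% of the variance among the 24 tumours (permutation p = 0.0544) and fibre for 6.53% (permutation p = 0.631).

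Tumours were set against the arrays labelled scraped mesothelium to ask what the malignant tissue gained and lost. Passing rises were 11 of 30 cell cycle genes, 2 of 21 mesenchymal genes and 3 of 21 inflammatory genes. Most genes of liver fell, 10 of 12, and 19 of 24 liver genes lay among the 500 brightest named genes of the scraped arrays. On those 2 arrays Apoa2 (an apolipoprotein) lay at 10.01 and Sftpc (a lung surfactant protein) at 8.88. Among mesothelial and epithelioid markers Krt18 lay at 7.93, Msln at 4.46 and Cdh1 at 4.13, while Wt1 (-4.85) and Calb2 (-4.24) were not well above background on either. Limma called 1005 genes, 333 higher and 672 lower in 24 tumours, 4513 at an unadjusted p under 0.05. With normexp background correction and quantile normalization the split was 200 higher and 1293 lower, and with median scaling 166 and 866. Counting each control array, as first planned, gave 4755.

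**Figure D4:**
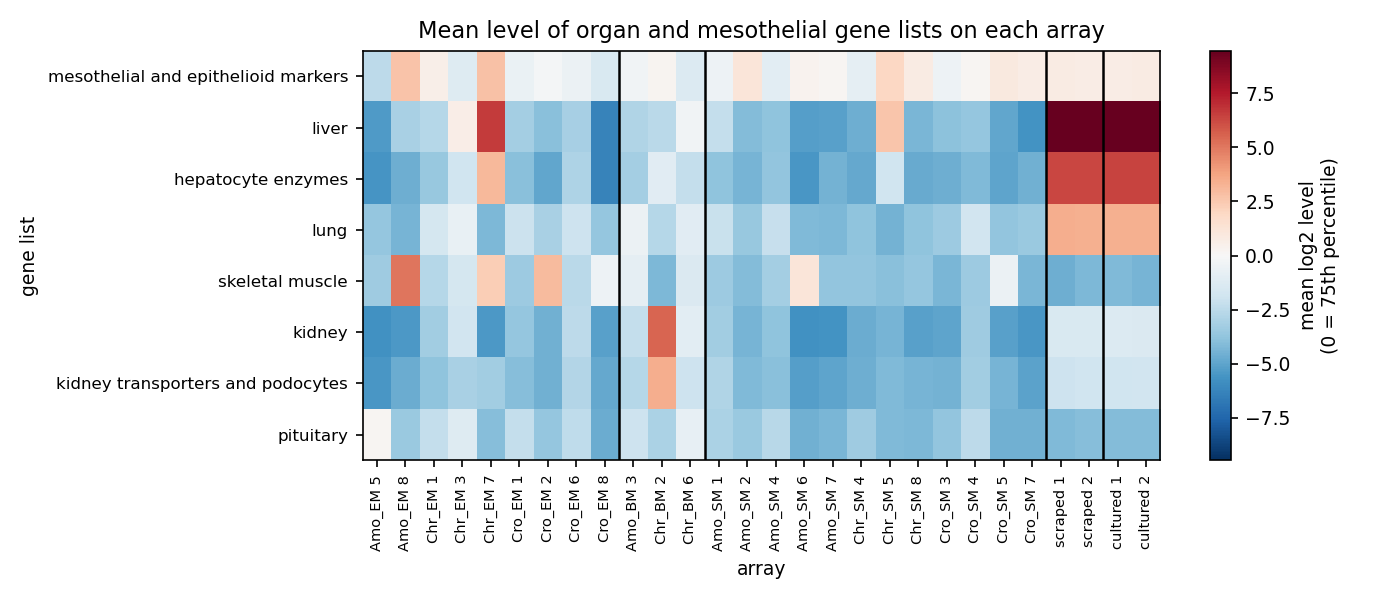
Mean log2 level (colour; 0 is the array's 75th percentile) of 8 lists of organ and mesothelial genes on each of the 28 arrays, ordered by histology code, with vertical lines between groups. Liver, hepatocyte and lung lists were highest on the 4 control arrays, kidney lists in Chr_BM 2 (kidney mean 5.54) and skeletal muscle in Amo_EM 8 (5.07).

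The largest rises were those of Sncg (gamma-synuclein, 8.59 ± 1.68, SE), Prrx1 (a mesenchymal homeobox factor, 8.42 ± 1.90), Twist1 (an inducer of epithelial-mesenchymal transition, 8.36 ± 1.92), Ccn4 (a Wnt-induced matricellular protein, 8.33 ± 2.22) and Penk (proenkephalin, 8.21 ± 1.98). Eno2 (neuronal enolase, 8.05 ± 1.26), Crabp2 (7.81 ± 1.93), Spp1 (osteopontin, 7.50 ± 1.85), Steap1 (7.49 ± 1.60) and Fcrl2 (7.36 ± 1.49) followed. Where neither scraped array was well above background the fold is a lower bound: at least 381-fold for Sncg, 335 for Prrx1, 326 for Twist1, 322 for Ccn4, 296 for Penk, 262 for Eno2 and 180 for Steap1. These bounds come from group means and do not take in the SE. Ccn4 (adjusted p = 0.0372) missed the threshold without scraped array 1 (adjusted p = 0.0516). Of 30 cell cycle genes 11 rose and 27 passed over the list alone, with a median of 3.93 (camera adjusted p = 2.1e-21; adjusted p = 0.307 with an estimated correlation). They included Ttk (6.33 ± 1.25, at least 80.6-fold), Bub1b (5.39 ± 1.24, at least 41.9-fold), Top2a (topoisomerase II, 5.33 ± 1.34) and Cdk1 (5.17 ± 1.2). Chemokine genes Ccl7 (6.48 ± 1.68, at least 88.8-fold) and Ccl2 (5.06 ± 1.34), both attractants of monocytes, rose with Spp1, 3 of 21 in the inflammatory list (adjusted p = 0.613 with an estimated correlation). The glycolytic enzymes Pkm (4.30 ± 1.01) and Hk1 (2.68 ± 0.58) rose, 2 of 20 in their list (median 2.61; adjusted p = 0.602 with an estimated correlation). Cdkn1a (p21, a cell cycle inhibitor) rose by 3.43 ± 0.96, and 1 of 12 tumour suppressors passed.

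Prrx1 and Twist1 were the 2 of 21 mesenchymal genes that passed over all genes, and 7 rose and 1 fell over the list alone (median 2.53; adjusted p = 0.577 with an estimated correlation). Matrix genes had a median of 2.79 (adjusted p = 6.0e-05; adjusted p = 0.602 with an estimated correlation) with none of 22 past the test. Ccn2 was 4.38 ± 1.80 (SD, n = 24) in tumours and 0.11 on the scraped arrays, a difference of 4.28 ± 1.47 (SE; 95% confidence interval 1.39 to 7.16), limma adjusted p = 0.131. Wt1 differed by 3.64 ± 1.62 (adjusted p = 0.30), Cdkn2a by 2.61 ± 1.27, Msln by 1.62 ± 2.68, Nf2 by 0.62 ± 1.07, Ctnnb1 by 0.56 ± 1.01, Cdkn2b by -0.08 ± 1.24 and Bap1 by -1.07 ± 0.83. None of these 7 passed. Called lists without a passing member were Wnt (1.21), macrophages (1.53), smooth muscle (1.35) and red blood cells (-2.30), with adjusted p of 0.602, 0.772, 0.495 and 0.602 with an estimated correlation. With normexp Wnt (adjusted p = 0.0970), smooth muscle (0.0547), red blood cells (0.0781), inflammatory genes (0.0875) and NRF2 (0.326) were not called. The list of mesothelial markers had a median of -0.27 and was not called (adjusted p = 0.519), and the pancreas list had a median of 1.46 against a mean of 0.20. Further uncalled lists had medians of 0.58 for YAP targets, 0.78 for TGF-beta, 1.22 for growth factors, 1.40 for MHC class II, 0.97 for T cells, -0.32 for B cells, 0.52 for neutrophils, 1.24 for mast cells, -0.43 for endothelial cells and 2.19 for skeletal muscle. The adipocyte list had a median of 0.34 against a mean of -0.60. Of the lists chosen after the data were seen, kidney (-2.98), kidney transporters and podocytes (-1.62), brain (1.28), testis (1.42), heart (0.96), intestine (0.24) and pituitary (1.62) were not called.

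Among the falls, the largest were those of liver proteins: the major urinary proteins Mup4l4 (-14.95 ± 2.32), Mup4l3 (-14.77 ± 1.94), Mup4l1 (-14.33 ± 2.07) and Mup4 (-13.64 ± 1.34), and the cytochromes Cyp3a2 (-14.41 ± 1.69), Cyp2c13 (-14.32 ± 1.54) and Cyp2c6v1 (-13.93 ± 3.35). Ugt2b (-14.11 ± 2.83), Gc (vitamin D binding protein, -13.72 ± 3.72) and Mug2 (-13.65 ± 3.13) followed. Of 12 liver genes 10 fell, median -12.57 (camera adjusted p = 4.2e-18; adjusted p = 0.123 with an estimated correlation), with Ttr at -13.61, Apoa2 at -13.55, Ahsg at -13.43 and Ambp at -13.40. A list of hepatocyte enzymes chosen after the data were seen fell for 9 of 12 members (median -10.62, adjusted p = 0.0183 with an estimated correlation). A lung list, also chosen then, fell for 4 of 6 (median -6.26, adjusted p = 0.0183 with an estimated correlation). As both were chosen after these data were seen, their p-values are no independent support. Iron handling had 6 of 22 genes lower (median -1.53; adjusted p = 0.111 with an estimated correlation): the plasma proteins Hp (haptoglobin, -10.90 ± 2.73) and Hpx (hemopexin, -10.88 ± 2.17), Hamp (hepcidin, -9.92 ± 1.60) and Tfr2 (-7.92 ± 1.68) were among them, all made by liver. Cat (catalase, -5.85 ± 1.59) fell in the NRF2 list (median -0.77; adjusted p = 0.565 with an estimated correlation) and Cela1 (an elastase, -6.17 ± 1.67) in the pancreas list.

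**Figure D5:**
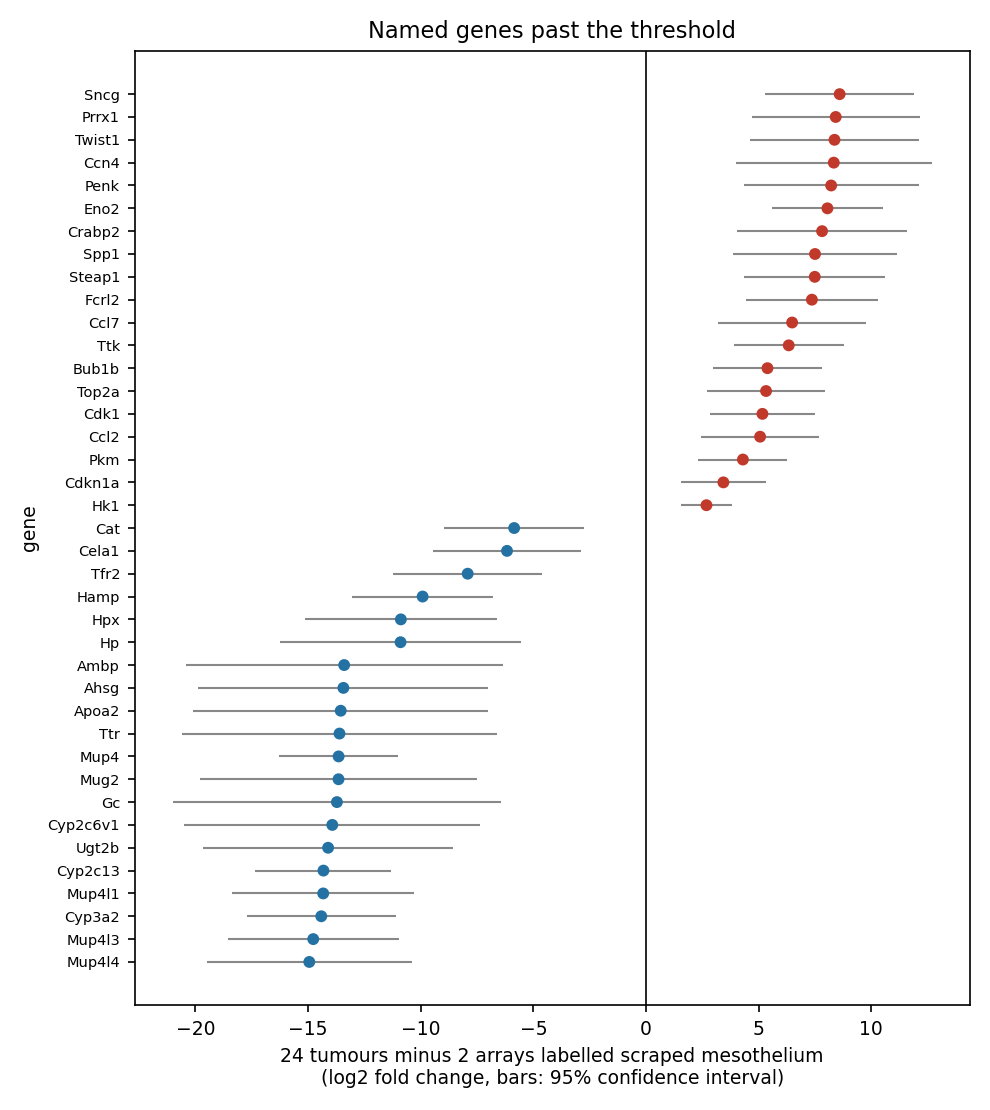
Log2 fold change of named genes past the threshold, 24 tumours minus 2 arrays labelled scraped mesothelium; points are limma estimates, bars 95% confidence intervals, red higher and blue lower in tumours. The estimates run from -14.95 (Mup4l4) to 8.59 (Sncg).

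With normexp and quantile normalization several of these rises no longer passed while keeping their sign. Sncg became 4.49 (adjusted p = 0.123), Prrx1 4.65 (0.163), Twist1 4.98 (0.0746) and Ttk 3.0 (0.0732), as did Ccn4, Penk, Crabp2, Steap1, Fcrl2, Bub1b, Top2a, Ccl7 and Ccl2. Eno2 at 3.93 (adjusted p = 0.0241) and the falls named above still passed there. The fold bounds above therefore hold for the main scale alone. With median scaling Top2a, Pkm, Hk1, Ccl2 and Cdkn1a did not pass. With quantile normalization of processed signals Cat (adjusted p = 0.120), Cela1 (0.0600), Top2a (0.0579) and Ccl2 (0.0534) did not, and with the mean of probes Penk, Bub1b, Hk1, Cdkn1a and Cela1 did not. Precision is limited by 2 control arrays of 1 pair, which differed by less than the scanner error and were averaged to 1 sample.

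EM tumours alone differed from the scraped arrays in 703 genes, 216 higher and 487 lower (4160 at an unadjusted p under 0.05), and in 3882 with each control array counted. The largest rises were Eno2 (8.58 ± 1.30, at least 378-fold), Twist1 (7.87 ± 1.98, at least 232-fold), Crabp2 (7.83 ± 1.99), Prrx1 (7.69 ± 1.97, at least 203-fold), Sncg (7.65 ± 1.74, at least 198-fold) and Flnc (filamin C, 7.47 ± 1.31, at least 177-fold). Steap1 (7.25 ± 1.65, at least 153-fold), Fcrl2 (6.86 ± 1.54), Lgals1 (galectin-1, 6.58 ± 1.25) and Fbln2 (fibulin-2, 6.52 ± 1.64) followed. Cell cycle genes rose for 8 of 30 members and 25 over the list alone, median 3.82 (adjusted p = 0.327 with an estimated correlation), with Ttk at 6.15 (at least 71.1-fold), Bub1b at 5.21 (at least 36.9-fold), Cdk1 at 4.91 and Ccna2 at 4.83 (at least 28.4-fold). Pkm (4.45) and Hk1 (2.57) rose. The falls were led by Mup4l3 (-14.87), Mup4l4 (-14.70), Mup4l1 (-14.51), Cyp2c13 (-14.14), Cyp3a2 (-13.77), Mup4 (-13.38), Ugt2b (-13.36), Apoh (-13.32), Cyp2c6v1 (-13.19) and Mug2 (-13.17). In the liver list 4 of 12 fell (12 over the list alone), with Apoa2 at -12.80, Fgb at -12.04, Apoc3 at -11.07 and Cyp2c11 at -10.99, and Hpx (-10.03), Hamp (-9.14), Tfr2 (-7.20) and Cela1 (-6.42) fell too. Skeletal muscle genes had a median of 3.76 (adjusted p = 0.00174; adjusted p = 0.637 with an estimated correlation), none past the test. Leaving out scraped array 1 raised the adjusted p of Crabp2 (0.0547), Prrx1 (0.0511), Fcrl2 (0.0596) and Ccna2 (0.0557) past the threshold, and leaving out scraped array 2 that of Twist1 (0.0504). Fitted with these groups alone the count was 13, and 11 named genes did not pass with normexp (Twist1, Crabp2, Prrx1, Sncg, Steap1, Fcrl2, Fbln2, Ttk, Bub1b, Cdk1 and Ccna2). With normexp the differences of Twist1 (4.62), Steap1 (3.69), Ttk (2.78), Prrx1 and Sncg lay below the logarithms of their fold bounds. The bounds of EM tumours against scraped therefore hold for the main scale alone. With median scaling Bub1b, Cdk1, Ccna2, Pkm and Hk1 did not pass. With quantile normalization of processed signals Fgb (adjusted p = 0.0529), Cela1 (0.0686), Bub1b (0.0834) and Ccna2 (0.0721) did not, and with the mean of probes Fbln2, Ttk, Bub1b, Ccna2, Hk1, Apoa2 and Cela1 did not. Ccn2 differed by 3.02 ± 1.52, adjusted p = 0.430.

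SM tumours differed from the scraped arrays in 1317 genes, 479 higher and 838 lower (4748 at an unadjusted p under 0.05), and in 4812 with each control array counted. Passing rises were 17 of 30 cell cycle, 4 of 21 mesenchymal and 2 of 22 matrix genes. Sncg (9.53 ± 1.71, at least 731-fold), Penk (9.31 ± 2.02, at least 632-fold), Prrx1 (9.08 ± 1.94, at least 530-fold), Twist1 (9.0, at least 506-fold) and Ccn4 (8.82 ± 2.26, at least 452-fold) led, before Eno2 (8.28, at least 308-fold), Crabp2 (8.22), Fcrl2 (8.01), Steap1 (8.0, at least 256-fold) and Fbln2 (7.85). Of 21 mesenchymal genes 4 rose (median 3.09; adjusted p = 0.536 with an estimated correlation), with Snai1 (4.85 ± 1.31) and Twist2 (4.07 ± 1.11, at least 16.7-fold) beside Prrx1 and Twist1. Of 22 matrix genes Lum (7.85 ± 2.17) and Dcn (decorin, 4.41 ± 1.19) rose (median 3.51; adjusted p = 0.565 with an estimated correlation), and without scraped array 1 Lum did not pass (adjusted p = 0.0618). Of 30 cell cycle genes 17 rose (median 4.60; adjusted p = 0.223 with an estimated correlation), with Ttk at 7.11 (at least 138-fold), Top2a at 6.24, Bub1b at 6.09 (at least 68.2-fold) and Cdk1 at 5.87. Ccn2 rose by 5.27 ± 1.5 (95% confidence interval 2.33 to 8.21; adjusted p = 0.0457), but not with normexp (4.84, adjusted p = 0.0661) or median scaling. Whether Ccn2 differs between SM and EM tumours is tested directly above.

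Spp1 (7.81), Ccl7 (7.42, at least 170-fold) and Ccl2 (5.90) rose in SM tumours against scraped, as did Adm (adrenomedullin, 4.88 ± 1.31), Pkm (4.58), Hk1 (2.76), Fgfr1 (4.28 ± 1.23), RT1-DMa (an MHC class II chaperone chain, 3.66 ± 0.98) and Cdkn1a (3.78). Wwc1 fell (-5.35 ± 1.36). The falls were led by Mup4l4 (-15.45), Cyp3a2 (-15.25), Gc (-15.20), F2 (prothrombin, -15.17), Mup4l3 (-15.06), Ugt2b (-14.89), Cyp2c6v1 (-14.84), Cyp2c13 (-14.69), Mup4l1 (-14.68) and Ambp (-14.62). Cyp3a2 was not well above background on any of 12 SM arrays, at least 38696-fold lower. In the liver list 10 of 12 fell, with Ttr and Apoa2 at -14.45 and Ahsg at -14.44. Hp (-11.39), Hpx (-11.19), Hamp (-10.74), Tfr2 (-8.79), Cela1 (-6.43) and Cat (-5.86) fell too. With normexp 14 named genes did not pass: Sncg, Penk, Prrx1, Ccn4, Crabp2, Steap1, Ccn2, Top2a, Bub1b, Lum, Fgfr1, Ccl7, Snai1 and Twist2. There the differences of Sncg (5.33), Penk (5.45), Prrx1 (5.19) and Twist2 (1.05) lay below the logarithms of the fold bounds given above. The bounds of SM tumours against scraped therefore hold for the main scale alone. With median scaling RT1-DMa, Ccn2, Adm, Hk1, Fgfr1 and Cdkn1a did not. With quantile normalization of processed signals Cat (adjusted p = 0.134), Cela1 (0.0501), Lum (0.0602) and Fgfr1 (0.0656) did not pass, nor did Snai1, Cdkn1a and Cela1 with the mean of probes.

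Against the arrays labelled cultured mesothelium limma called 1078 genes, 375 higher and 703 lower (4639 at an unadjusted p under 0.05), and 4903 with each control array counted. On these arrays, too, 19 of 24 liver genes lay among the 500 brightest named genes. Prrx1 (8.68 ± 1.90, at least 404-fold), Penk (8.30 ± 1.98, at least 316-fold), Crabp2 (8.22), Sncg (8.21, at least 290-fold), Ccn4 (8.18, at least 289-fold), Eno2 (8.14 ± 1.26, at least 278-fold), Fcrl2 (7.69, at least 207-fold), Spp1 (7.44), Ddit4l (an mTOR inhibitor, 7.29 ± 1.57, at least 157-fold) and Twist1 (7.29) rose most. Cell cycle genes rose for 11 of 30 members (25 over the list alone), median 3.99 (adjusted p = 0.327 with an estimated correlation), with Ttk at 6.47 (at least 88.7-fold), Cdk1 at 5.19, Top2a at 5.18 and Ccna2 at 5.13 (at least 35-fold). Pkm (4.16), Cdkn1a (3.62), Hk1 (2.77), Ccl2 (5.10) and Skil (a TGF-beta antagonist, 2.98 ± 0.75, at least 7.89-fold) rose, and without cultured array 1 Skil did not pass (adjusted p = 0.0646). The falls were led by Mup4l4 (-15.08), Mup4l3 (-14.95), Cyp3a2 (-14.55), Mup4l1 (-14.43), Cyp2c13 (-14.28), Ugt2b (-14.13), Cyp2c6v1 (-14.06), Mup4 (-13.93), Mug2 (-13.91) and Gc (-13.87). Ttr (-13.52), Ahsg (-13.52), Ambp (-13.49), Apoa2 (-13.46), Hp (-11.11), Hpx (-10.94), Hamp (-9.84), Tfr2 (-8.00), Cat (-6.10) and Cela1 (-5.96) fell too. Ccn2 differed by 4.28 ± 1.47, adjusted p = 0.127. With normexp Prrx1, Penk, Crabp2, Sncg, Ccn4, Ddit4l, Twist1, Skil, Top2a, Ccna2 and Ccl2 did not pass, and with median scaling Skil, Top2a, Pkm, Hk1, Ccl2 and Cdkn1a did not. Skil differed by 0.974 with normexp and 2.23 with quantile normalization of processed signals, and Prrx1 by 4.63 with normexp. These lie below the logarithms of their fold bounds, so the bounds of this comparison hold for the main scale alone. With quantile normalization of processed signals Cat (adjusted p = 0.0948), Cela1 (0.0692), Ccn4 (0.0526), Skil (0.104), Top2a (0.0698) and Ccl2 (0.0531) did not pass, nor did Penk, Skil, Ccna2, Cdkn1a and Cela1 with the mean of probes.

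The last comparison set the cultured against the scraped arrays. With each pair averaged it sets 1 sample against 1 with the spread of the tumours (median SE 1.61), so the 0 genes limma called, with 2 at an unadjusted p under 0.05, do not show that the arrays were alike. Limma fitted to the 4 control arrays alone also called 0, with 4881 at an unadjusted p under 0.05. Ccn2 was 0.10 on the cultured and 0.11 on the scraped arrays, and Msln was 4.46 on both. Scraped and cultured arrays differed by 1.22 to 1.32 times the scanner's own error, more than the arrays of the scraped (0.826) and cultured pair (0.670), while pairs of tumours differed by 3.53 to 11.1 times. Of 26 lists only cell cycle was called (median 0.07, adjusted p = 0.0498), and not with an estimated correlation (adjusted p = 0.843) or with normexp (adjusted p = 0.807).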

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

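The tests of liver RNA, of the scaling and of a shared RNA on the control arrays, of low signal, and the 4 tests of the 84 genes were chosen after the results they concern were seen. A tumour was singled out when its gap to the nearest other tumour of its group was too large a part of the group's range by Dixon's test. This held for 30 values among 140 groups tested, where chance gives about 1 in 20.

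Amo_EM 5 stood apart in 11 of them, among EM as well as Amo tumours for all but growth factors (EM only). Its log2 level was -4.50 for Msln, -1.76 for the mesenchymal list, -1.91 for collagens and matrix, -2.72 for Wnt, -2.38 for TGF-beta and -2.76 for growth factors. Chr_BM 2 stood apart among Chr tumours with low means for mesenchymal genes (-0.69), TGF-beta (-1.22), inflammatory genes (-1.55) and macrophages (-0.82). On Chr_BM 2, 9 of 10 kidney transporter and podocyte genes lay over 2 log2 units above the highest other tumour, which is in line with kidney tissue in that sample. Miox exceeded the highest other tumour by 8.61, Slc22a8 by 5.25, Slc34a3 by 4.80 and Cubn by 4.67, and Calb1 was the exception (-0.87). On Amo_EM 5, 3 of 12 pituitary genes did so, with levels of 8.89 for Prl, 3.61 for Gh1, 3.94 for Pomc and 1.28 for Scg2, so tissue of another organ stays open there. Low signal is argued against as the cause on both arrays: at least 62.7% of their probes lay well above background. A swapped sample was not tested, and no biological explanation was tested.

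Liver genes led the control arrays. Of 24 liver genes 19 were among the 500 brightest named genes of the cultured arrays, 0 among those of the tumour mean and 19 among those of the scraped arrays. Of 6 lung genes 1 was, and of 5 intestine genes 1. Scaling is argued against as the cause, since the liver median stayed at -9.45 for tumours minus scraped after normexp and quantile normalization. Scraped and cultured arrays differed by 1.28 times the scanner's own error, less than tumours do but more than the arrays of either pair (0.826 and 0.670), so 1 RNA on all 4 arrays stays open. Whether RNA of liver took the place of mesothelial RNA or was mixed with it cannot be told. The list of mesothelial and epithelioid markers had a median difference of -0.27, and 7 of 18 were lower on the scraped arrays. It also holds epithelioid genes such as Krt18 and Cdh1, so its level does not speak for mesothelial RNA alone. Wt1 and Calb2 were not well above background on either scraped array. Strain, slide and scan day coincide with the controls and stay open.

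The 84 genes higher in BM than in SM tumours were dim, with a median percentile of SM level of 2.09. Without the 3 tumour arrays of lowest signal (Chr_BM 6, Chr_EM 3 and Cro_EM 6) 66 of the 84 passed. The median difference of all 84 was then 3.996 (median SE 0.788). It was 4.25 (0.802) for the 66, but these were picked by passing there, so this value is no added support. The calls of the 66 did not need those 3 arrays. The 84 were picked with the arrays included, however, so low signal stays open as a cause. For the other 18 the calls ended there and the difference went from 3.66 (0.773) to 3.06 (0.698). Without Chr_BM 6 alone 10 of the 84 passed: the median SE rose from 0.796 to 0.918, while the median difference was 4.01 before and 4.04 after. On Amo_BM 3 and Chr_BM 2, with 91.0% and 76.2% of probes well above background, 79 and 82 of the 84 lay over 2 log2 units above the SM mean, but the genes were picked for being high over these arrays. A part of the scaling in raising dim probes stays open: the median difference of the 84 was 4.01 (median SE 0.796) and became 3.50 (0.731) with median scaling, 2.33 (0.660) with quantile normalization and 0.56 (0.175) with normexp, with 0, 2 and 0 past the threshold. All 84 passed without Chr_BM 2, but 5502 genes were called there, which loosens the Benjamini-Hochberg cutoff, so passing is no added support. The median difference of the 84 was 3.50 (median SE 0.874) without that array, so it did not need Chr_BM 2. The 84 were picked with that array included, however, so a part of kidney tissue in Chr_BM 2 stays open. A biological difference between BM and SM tumours stays open, with 3 BM arrays.

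The other tumours stood apart in single values. Chr_EM 7 was high in iron handling (2.64, among EM and among Chr tumours), skeletal muscle (2.30) and red blood cells (2.73). Chr_SM 5 stood apart in YAP targets (0.70) and growth factors (-0.44), and Amo_SM 7 in adipocytes (2.30). On Chr_BM 6, 34.0% of probes lay well above background, and on Cro_EM 6, 40.03%. Cro_EM 6 was low in Ctnnb1 (-1.61) and Bap1 (-2.04), and Cro_EM 8 stood apart in Wt1 (-3.13) and iron handling (-0.29). Cro_SM 3 was low in inflammatory genes (-0.14) and Cro_SM 7 high in macrophages (5.16).

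Random splits of the same tumours, 100 drawn per comparison with the real one, were counted. For the 84 genes of BM against SM, 2 of 100 splits gave as many, the real one included. Groups were drawn without regard to slide or fibre, and the share was not adjusted for the other comparisons split. It therefore does not exclude chance. The real count itself was 0 with slide as a fixed block, 0 with the replicate block and 0 in 11 of 24 cases of leaving out 1 tumour. The highest other split gave 9411, which points to a structure of the samples whose cause was not tested. For the other comparisons the real count was 0, so that 100 of 100 splits gave as many by construction, and these counts say nothing about chance. The highest other split gave 0 for SM against EM, 15359 for BM against EM, 8934 for Amo against Chr, 1 for Amo against Cro and 7995 for Chr against Cro. On genes at an unadjusted p under 0.05, as many as in the real split came from 18 of 100 splits for SM against EM, 41 for BM against EM, 58 for Amo against Chr, 39 for Amo against Cro and 51 for Chr against Cro, so chance cannot be excluded for those numbers.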

How the results depend on the processing

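Array weights, scan day as the block of the fibre comparisons and leaving out 2, 3 or 6 arrays were chosen after the data were seen, as was averaging the control pairs, so that counting each control array is the analysis as first planned. Values are genes past the threshold, and the cause was not tested unless stated. Leaving out 1 array gave 0 to 2 genes for SM against EM (1 without Amo_BM 3, 2 without Chr_BM 2), 0 to 30 for BM against EM (30 without Cro_EM 6), 0 to 5502 for BM against SM (5502 without Chr_BM 2), 0 to 118 for the interaction (118 without Amo_EM 8) and 0 for the 3 fibre comparisons. For comparisons with controls only the 4 control arrays were left out 1 at a time, so these ranges do not speak for the tumours: 1005 to 1054 for tumours against scraped, 703 to 761 for EM and 1317 to 1389 for SM tumours against scraped, 1078 to 1161 for tumours against cultured, and 0 for cultured against scraped. Normexp and quantile normalization gave 3 (SM against EM), 0 (BM against SM), 64 (interaction) and 1336 (EM against scraped). Quantile normalization gave 1 (BM against EM), 4 (BM against SM) and 34 (interaction). Median scaling gave 0 (BM against SM) and 13 (interaction), eBayes with trend and robust 0 and 5, and the Uty covariate 142 and 1. BM against SM gave 0 with the filter on 50% of the arrays, slide as a fixed block or the replicate block. SM against EM gave 1 with the replicate block, 2 without the BM tumours and 4 within Amo. With only these groups in the model EM against scraped gave 13 and SM against scraped 3687, and BM tumours alone against scraped gave 0. Counting each control array gave 4755 (tumours), 3882 (EM) and 4812 (SM) against scraped and 4903 against cultured, and with the replicate block 5131, 4411, 4858 and 5311; more control samples are counted there by construction. Without Amo_EM 5 and Chr_BM 2 the counts were 5458 (BM against SM), 2174, 1694 and 2247 (tumours, EM and SM against scraped) and 2236 (against cultured). Without the 3 arrays of low signal they were 63 (BM against EM), 127 (BM against SM), 4 (interaction), 1583 and 1150 (tumours and EM against scraped) and 1672 (against cultured). Without all 6 they were 1 (SM against EM), 0 (BM against SM), 7 (interaction), 3464, 2974 and 3414 (tumours, EM and SM against scraped) and 3511 (against cultured). Array weights gave 14 (SM against EM), 10640 (BM against EM), 14601 (BM against SM), 11 (Amo against Chr) and 15 (Chr against Cro). The weights of the BM tumours were 3.24 for Amo_BM 3, 0.263 for Chr_BM 2 and 0.309 for Chr_BM 6. The 2 BM counts with weights therefore rest largely on 1 tumour. Of 286 list tests 106 were called, 0 with an estimated correlation, 82 with normexp and 104 without the 6 arrays. Histology held 11.6% of the variance with normexp (permutation p = 0.0845), 9.98% with 1 minus Pearson correlation (0.325) and 16.6% without the 6 arrays (0.114), and fibre 8.18%, 5.63% and 8.86%. Of 252 values of named genes the 165 past the threshold kept their sign in every setting. Of the 87 others 44 changed sign in at least 1 setting and 30 on leaving out 1 array, all with an adjusted p of 0.143 or more. Of the 165, 54 lost the threshold with normexp, 27 with median scaling, 23 with quantile normalization and 20 with the mean of probes. Of 24 pairs of tumours with the same number in different fibre codes the median correlation was 0.238, against -0.06 for other pairs across codes, 17 of 24 had one over 0.1, and 2 of 24 tumours correlated best with their own number. Signal over background limits genes near the floor, where fold bounds are given in place of folds.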

Other observations

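The test of Ccn2 with the matrix list was chosen before its result was seen, as 1 of 6 lists, and no test in this part was chosen after.

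Ccn2 encodes a matricellular protein, and a shared level with matrix genes over the tumours beyond histology and fibre was the hypothesis. Over 24 tumours Ccn2 and the mean of collagens and matrix had Pearson's r = 0.434 (permutation p = 0.0320, adjusted p = 0.0384 over 6 lists) and Spearman's rho = 0.343 (permutation p = 0.102). Without the 2 tumours farthest from the median r was 0.175, so the relation rests on those tumours. After histology and fibre were removed r was 0.250 (permutation p = 0.236), so these data do not decide whether the level is shared. Within scan day 2 r was 0.254 (n = 8) and within scan day 4 it was 0.575 (n = 12).

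The TGF-beta list had the highest r of the 6 lists. Its r with Ccn2 was 0.638 (permutation p = 0.000230, adjusted p = 0.00138) with rho = 0.611 (permutation p = 0.00192), and 0.619 without the 2 farthest tumours. After histology and fibre were removed r was 0.562 (permutation p = 0.00311, adjusted p = 0.0187) with rho = 0.476 (permutation p = 0.0199). The permutations after removal treat the residuals as free values and ignore the fitted histology and fibre terms. For every list the p-values after removal are therefore too small. They do not decide whether a relation goes beyond histology and fibre. Within scan day 2 r was 0.453 and within scan day 4 it was 0.731. Without the 6 arrays r was 0.373 before and 0.464 after removal. For macrophages r was 0.597 (adjusted p = 0.00447) and 0.446 after removal (permutation p = 0.0280, adjusted p = 0.0561). For mesenchymal genes r was 0.488 (adjusted p = 0.0199) and 0.344 after removal (adjusted p = 0.147), for cell cycle 0.516 (adjusted p = 0.0176) and 0.479 (adjusted p = 0.0558), and for YAP targets -0.15 and -0.14 (adjusted p = 0.479 and 0.521). Before removal rho was 0.297 (permutation p = 0.158) for mesenchymal and 0.395 (permutation p = 0.0576) for cell cycle genes. Their r without the 2 farthest tumours was 0.278 and 0.471. Without the 6 arrays the cell cycle r was -0.16, and that of collagens and matrix 0.245 before and 0.0972 after removal.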
